A study of Rattus norvegicus with 24 samples.

How the data were processed

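Cumulus-oocyte complexes, each an oocyte with its surrounding cumulus granulosa cells, came from 24 adult female Sprague Dawley rats, with 1 array per rat. The labels put 6 rats in each of 4 groups: untreated control, GnRH, GnRH followed by equine chorionic gonadotropin (GnRH+eCG), and both followed by human chorionic gonadotropin (GnRH+eCG+hCG, called the hCG group). RNA was amplified and labelled with biotin before hybridization to 1-colour bead arrays, per the labels. Times between hormones and collection are not given in the sources used here. Rat numbers come from the labels and no number occurs in more than 1 group.

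The deposited signals are intensity values on a linear scale, summarised per probe with BeadStudio per the submitters' processing notes, whose version and settings are not given in the sources used here. No value lay near or under 0 and the arrays kept different medians, so no background subtraction or normalization between arrays was seen in them. The deposited detection columns hold a fraction from 0 to 1 that rose with signal on all 24 arrays. The file note, per the file headers, calls this a p-value, but it was read as a score equal to 1 minus the detection p. Both deposited tables list 22226 probes. Their identifiers matched for 21946 probes, and the other 280 were joined on all 24 signals with a tolerance of 0.002 on the log2 scale. These 280 probes were tested but not named.

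Gene symbols came from the platform annotation given for this work, which can be old. It gave 1 symbol for 13599 probes, several for 0 and none for 8627, which are unnamed here and not without a gene. After the 280 joined probes were set aside, 13518 probes carried 13161 symbols. Gene identifiers of 13559 probes matched the RefSeq gene table of assembly GRCr8, which led to 0 changed symbols. No coordinates are printed, because the build behind the array is not given in the sources used here.

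Signals were background corrected and quantile normalized with neqc of limma 3.58.1 in R 4.3.3, with an offset of 16 and the background inferred from the detection p. Probes with a detection p under 0.01 on at least 6 of the 24 arrays were tested, which left 8082 probes, or 36.4%. A linear model with 1 mean per group was fitted to all 24 arrays with lmFit and eBayes, leaving 20 residual degrees of freedom. Benjamini-Hochberg adjustment ran over the 8082 probes in each of the 5 comparisons, with a threshold of 0.05. Adjusted p-values of single genes are from this limma fit. Values are log2 normalized signal, given as mean ± SD over n = 6 rats or as a log2 difference with its SE. Each gene was represented by its probe with the highest mean signal.

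A probe detected on no array of a group has only a bound there. Its fold is given as at least N-fold, from the bright group's mean over the dim group's mean of, per array, the higher of the lowest detected signal and the probe's own signal. Named genes followed a rule: the 10 largest rises and 10 largest falls past the threshold whose 6 values lay wholly on one side of the other 6, with detection in both groups. Up to 5 rising and 5 falling genes detected in only 1 of the compared groups were added, past the same threshold and with the same separation, ranked by the bound. Where fewer than 5 genes passed, the 5 with the smallest p are given as values. From each gene list came the 2 to 4 members with the smallest adjusted p in the hCG group against GnRH+eCG, and all measured cumulus expansion members. Genes outside this rule are said to be chosen after their values were seen.

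Of 21 gene lists, 6 hold markers of other cell types. Most lists were measured only in part, such as 8 of 12 cumulus expansion genes and 4 of 20 inflammation genes. Of the markers, 4 of 14 for leukocytes, 2 of 7 for erythrocytes, 2 of 10 for endothelium and 3 of 14 for oviduct epithelium were measured. Lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation, with adjustment over 105 tests (21 lists in 5 comparisons). The fry test was run beside it. Groups, tests, gene lists, the naming rule and the alternatives were fixed before the data were examined, except the runs without GnRH rats 5 and 16, the array weights without hCG rat 24 and the tests of explanations for 3 patterns, which were chosen after seeing the data. These patterns were GnRH rats 5 and 16 standing apart, probes of GnRH+eCG against control keeping their sign in the hCG group against GnRH, and lower oocyte genes after hCG. Alternatives covered normalization, offset, filter, the variance model, array weights, the threshold, a block for rats 1 to 12 against rats 13 to 24, and leaving out each array. No slide or scan date was used here, so those sets of rat numbers, with 3 rats of each group in each, stood in for a batch. All 24 sample columns were used and 0 were left out.

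The model was tested on simulated arrays with 200 of 8082 probes changed. For GnRH against control it recovered 85.5% of 2-fold changes and 46.5% of 1.5-fold changes. For GnRH+eCG against GnRH these were 84.5% and 40.5%, and for GnRH+eCG against control 85.5% and 52%. For the hCG group they were 84.5% and 39.5% against GnRH+eCG, and 88% and 46% against control. The simulated noise was independent between probes and had 1 spread per probe on all arrays. Real arrays differed in weight and genes varied together, so these rates can be too favourable. Each simulated change was also the same on all arrays of a group, and recovery depends on the share of probes changed. With fewer than 200 changed probes it can be lower, and with many more, as called for the hCG group, higher. The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3.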

Results

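Gene expression was measured in cumulus-oocyte complexes of 24 rats, 6 in each of 4 groups: control, GnRH, GnRH+eCG and GnRH+eCG+hCG. GnRH stands for gonadotropin-releasing hormone, given to align the cycle. Equine chorionic gonadotropin acts much like follicle-stimulating hormone and drives follicle growth, and human chorionic gonadotropin acts at the luteinizing hormone receptor and triggers ovulation. Between 25.3% and 37.9% of probes were detected per array. Median raw signal was 176.7 to 235.4 in rats 1 to 12 and 140.5 to 180 in rats 13 to 24, and each of these sets held 3 rats of every group. Replicate arrays correlated at r = 0.914 to 0.981 in control, 0.885 to 0.982 in GnRH, 0.924 to 0.98 in GnRH+eCG and 0.93 to 0.987 in the hCG group, across probes, which are not independent replicates.

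The first principal component held 49.6% of the variance and parted the hCG group, at 41 to 49.8, from the other arrays. Control arrays lay at -34.2 to -17.5 and GnRH+eCG arrays at -23 to 4.1. GnRH rats 5 and 16 lay at 19.7 and 19, and the other 4 GnRH rats between -28.3 and -18.2.

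**Figure D1:**
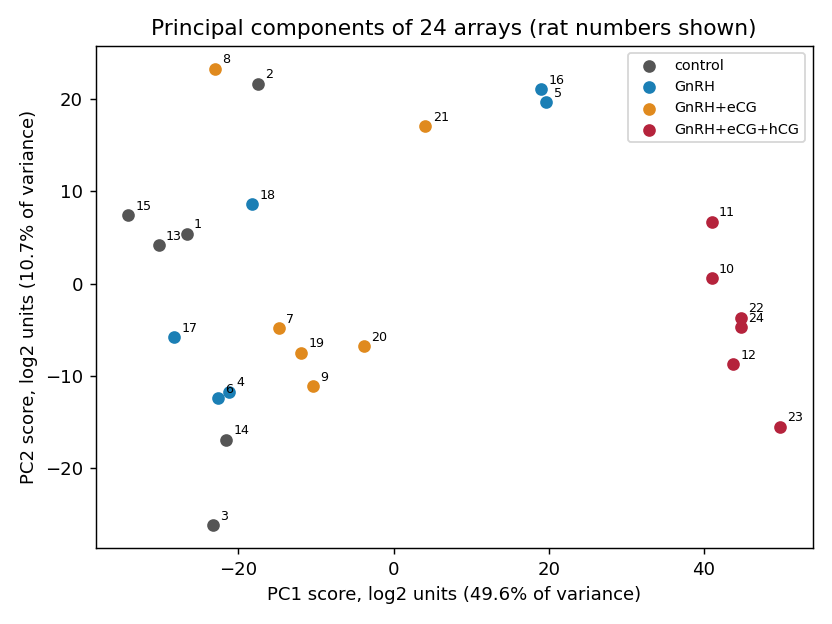
Scores of the 24 arrays on the first component (x axis, 49.6% of variance) and the second (y axis, 10.7% of variance), in log2 units, with 1 point per rat, its number beside it and colour for the group. The 6 hCG arrays lie at 41 or above on the first component, and GnRH rats 5 and 16 lie near 19 between them and the other arrays.

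Whether alignment of the cycle with GnRH alters the complexes was asked by comparing GnRH with control. No probe passed the threshold. The genes with the smallest p were Mrpl49, a mitochondrial ribosomal protein, with a log2 difference of 0.52 ± 0.12 (SE), Tram1 with 0.51 ± 0.12, Qsox1 with -0.68 ± 0.16, Ppp4r3a with 0.51 ± 0.12 and Akr1c3 with 2.32 ± 0.56, each at adjusted p = 0.377 by limma. Akr1c3 stood at 10.3 ± 1.47 in GnRH and 7.97 ± 1.09 in control (SD, n = 6 each, limma), so its difference came with a wide spread. Hemoglobin transcripts differed as a list of 2 genes, with a median log2 difference of 1.29.

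That hemoglobin list was called by camera (adjusted p = 0.0022), although 0 of its 2 members passed over all probes and 2 rose when adjusted over the list alone. Its call was lost with an estimated correlation (adjusted p = 0.183 with an estimated correlation). Oocyte genes, 16 of them measured, had a median of -0.51 (camera adjusted p = 1.1e-05; adjusted p = 0.444 with an estimated correlation), with 0 of 16 past the threshold over all probes and 0 adjusted over the list alone. Glycolysis had a median of 0.32 (0.000453; adjusted p = 0.348 with an estimated correlation), with 4 of 15 members up when adjusted over the list alone. The housekeeping list had a median of 0.24 (0.00911; adjusted p = 0.183 with an estimated correlation), with 1 of 9 up adjusted over the list alone. Without GnRH rats 5 and 16 the medians of these oocyte, glycolysis and housekeeping lists were -0.32, 0.18 and 0.12 (camera adjusted p = 0.00013, 0.0303 and 0.0349; adjusted p = 0.501, 0.506 and 0.226 with an estimated correlation), and that of the hemoglobin list 1.4 (4.77e-05; adjusted p = 0.0834 with an estimated correlation).

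For 5 further lists of GnRH against control the call was lost without GnRH rats 5 and 16. Cholesterol biosynthesis had a median of 0.45 (camera adjusted p = 0.00136; adjusted p = 0.456 with an estimated correlation) and -0.01 without those rats. The LH surge response had a median of 0.66 (0.0112; adjusted p = 0.348 with an estimated correlation) and 0.1 without them; its call was also lost without GnRH rat 5 alone (0.052). Cell cycle genes had a median of -0.24 (0.0134; adjusted p = 0.592 with an estimated correlation) and 0.02 without them. Theca and stroma markers had a median of 0.95 (0.0265; adjusted p = 0.424 with an estimated correlation) and 0.24 without them, and leukocyte markers 0.63 (0.0363; adjusted p = 0.444 with an estimated correlation) and 0.34 without them. That run was chosen after seeing the data. Leaving out single arrays also ended the calls of cell cycle (control rat 2, 0.0837; GnRH rat 5, 0.136; GnRH rat 16, 0.108), theca and stroma (control rat 3, 0.0633; control rat 14, 0.0538; GnRH rat 5, 0.0827) and leukocytes (control rats 3, 13 and 14 and GnRH rats 4, 5 and 18, 0.051 to 0.169). In rats 1 to 12 and rats 13 to 24 the medians were 0.19 and 0.72 for cholesterol biosynthesis and -0.31 and -0.08 for cell cycle.

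At an unadjusted p under 0.05 the limma fit of GnRH against control gave 961 probes, where 404 would be expected by chance. The 95% confidence interval lay within a 2-fold change for 91.2% of the 8082 probes and within a 1.5-fold change for 65.8%. The count was 0 with the rat-number sets as a block and 0 within each set.

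Whether ovarian stimulation adds to GnRH was asked by comparing GnRH+eCG with GnRH. No probe passed the threshold. The smallest p belonged to Pla2g4a, the cytosolic phospholipase that releases arachidonic acid for prostaglandin synthesis, at 8.55 ± 0.45 in GnRH+eCG and 7.5 ± 0.22 in GnRH (SD, n = 6 each, limma), with all 6 values above the other 6. Its log2 difference was 1.05 ± 0.18 (SE), at adjusted p = 0.0664. Olfml3 differed by 1.12 ± 0.21 (adjusted p = 0.076), Il13ra2 by 1.06 ± 0.21 (0.104), Dlgap1 by 0.78 ± 0.16 (0.112) and the amino acid transporter subunit Slc7a7 by 1.28 ± 0.28 (0.179).

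Among the lists, cumulus expansion genes had a median difference of 0.27 between GnRH+eCG and GnRH (camera adjusted p = 0.0134; adjusted p = 0.183 with an estimated correlation), with 1 of 8 members up adjusted over the list alone. Steroidogenesis had a median of 0.36 (0.00829; adjusted p = 0.348 with an estimated correlation) and cholesterol biosynthesis 0.24 (0.00661; adjusted p = 0.567 with an estimated correlation). Of the members of these lists adjusted over the list alone, 1 of 12 and 0 of 13 rose. Without GnRH rats 5 and 16 their medians were 0.62 and 0.55 (camera adjusted p = 0.000118 and 4.91e-14; adjusted p = 0.15 and 0.0875 with an estimated correlation). The cumulus expansion call was lost with median scaling (0.0759). Single arrays ended the calls of cumulus expansion (GnRH rat 17, 0.0545; GnRH+eCG rat 21, 0.0513) and cholesterol biosynthesis (GnRH rats 4, 6 and 17 and GnRH+eCG rat 21, 0.0806 to 0.208).

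For 4 further lists of GnRH+eCG against GnRH the call was lost without GnRH rats 5 and 16. Cyclic nucleotide and meiotic arrest genes had a median of 0.39 (0.0022; adjusted p = 0.152 with an estimated correlation) and 0.01 without those rats, and glycolysis -0.2 (0.0073; adjusted p = 0.444 with an estimated correlation) and -0.04. Adjusted over the list alone, 1 of 9 and 0 of 15 members passed, and the glycolysis call was also lost without GnRH+eCG rat 9 (0.0794) or GnRH rat 16 (0.156). Cell cycle genes had a median of 0.23 (0.000453; adjusted p = 0.444 with an estimated correlation) and 0.02 without them, and mural granulosa markers 0.42 (0.00988; adjusted p = 0.348 with an estimated correlation) and -0.03, with 0 of 21 and 0 of 7 adjusted over the list alone; the second call was also lost without GnRH rat 16 (0.0639). The cell cycle median was 0.53 in rats 1 to 12 and -0.02 in rats 13 to 24. Without those rats theca and stroma markers were called at 0.66 (camera adjusted p = 0.000881; adjusted p = 0.196 with an estimated correlation) and leukocyte markers at 0.7 (0.00199; adjusted p = 0.188 with an estimated correlation).

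The limma fit of GnRH+eCG against GnRH gave 431 probes at an unadjusted p under 0.05, with 404 expected by chance. The 95% confidence interval lay within a 2-fold change for 94.1% of probes and within a 1.5-fold change for 72.3%. The count was 0 with the rat-number sets as a block and 0 within each set, 4 with median scaling, 26 with array weights (12 when hCG rat 24, of weight 13.4, was left out after seeing the data), 3 without GnRH+eCG rat 7, 1 without GnRH+eCG rat 8 and 2 without GnRH rat 18.

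The combined effect of GnRH and eCG was asked against control. A small set of genes changed, 21 probes higher and 13 lower of 8082, or 17 and 8 named genes. Pla2g4a rose from 7.07 ± 0.33 to 8.55 ± 0.45 (SD, n = 6 each, limma), 2.79-fold, at adjusted p = 0.000282. Its 6 GnRH+eCG values all lay above the control values, which the naming rule required. Herpud1, an endoplasmic reticulum stress protein, rose by 1.21 ± 0.18 (SE, log2; adjusted p = 0.00204) and Olfml3 by 1.25 ± 0.21 (0.00881). Pla2g4a and Olfml3 were each detected on 3 of the 6 control arrays, so their rises are measured partly against signals at background. Butyrylcholinesterase, Bche, fell by 1.8 on the log2 scale, SE 0.34 (0.0136).

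Smaller rises were seen in Tp53i11 (log2 0.88), Bola3 (0.87), Gmfg (0.71), Bzw1 (0.54), Pak1ip1 (0.54), Mrpl49 (0.53) and the secretory cargo receptor Tmed10 (0.47), at adjusted p from 0.0121 to 0.0448. Ech1, Fbxl20 and the junction protein Afdn fell by 0.89, 0.67 and 0.63. Pde10a, a cyclic nucleotide phosphodiesterase detected on 4 GnRH+eCG arrays and 0 control arrays, was at least 1.83-fold higher (adjusted p = 0.0356). Sspn and Zfp346, detected on 0 GnRH+eCG arrays, were at least 3.27-fold and 1.51-fold lower (0.0352 and 0.0136). Leaving out 1 array ended the calls of Tp53i11, Bzw1, Pak1ip1, Mrpl49, Tmed10, Ech1, Fbxl20, Afdn, Pde10a and Sspn, each for 5 to 10 of the 12 arrays and at adjusted p up to 0.122, and that of Gmfg without GnRH+eCG rat 20 (0.06).

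Cholesterol biosynthesis genes had a median difference of 0.72 between GnRH+eCG and control (camera adjusted p = 2.59e-06; adjusted p = 0.348 with an estimated correlation), with 0 of 13 past the threshold over all probes and 9 up adjusted over the list alone. Steroidogenesis had a median of 0.6 (0.000331; adjusted p = 0.183 with an estimated correlation), with 7 of 12 up adjusted over the list alone. Of 8 cumulus expansion genes, 1 rose over all probes, the matrix proteoglycan Vcan (0.5, adjusted p = 0.0448 by limma). This Vcan call, near the threshold, was not rerun without single arrays. Adjusted over the list alone 4 rose (median 0.43, camera 0.00548, and adjusted p = 0.152 with an estimated correlation). Oocyte genes had a median of -0.33 (0.0073; adjusted p = 0.631 with an estimated correlation), with 0 of 16 past the threshold over all probes or adjusted over the list alone. That call was lost without control rat 2 (0.11), control rat 15 (0.115) or GnRH+eCG rat 20 (0.126), and the median was -0.06 in rats 1 to 12 and -0.65 in rats 13 to 24.

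Markers of other cells differed beside these groups. Erythrocyte markers had a median difference of 1.33 between GnRH+eCG and control (camera adjusted p = 0.00391; adjusted p = 0.194 with an estimated correlation), leukocyte markers 1.06 (0.00193; adjusted p = 0.223 with an estimated correlation) and theca and stroma markers 0.89 (0.00548; adjusted p = 0.288 with an estimated correlation). Counts adjusted over the list alone were 2 of 2, 3 of 4 and 3 of 7, and 0 members passed over all probes. In rats 1 to 12 these medians were 1.95, 0.73 and 0.28, and in rats 13 to 24 they were 0.7, 1.49 and 1.26. Cholesterol biosynthesis had medians of 0.46 and 0.85 in these sets.

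The count of 34 probes for GnRH+eCG against control was 35 with the rat-number sets as a block, but 0 within rats 1 to 12 and 15 within rats 13 to 24. It moved to 187 without GnRH rats 5 and 16, which belong to neither group and entered only through the shared spread, in a run chosen after seeing the data, and to 540 with array weights (480 without hCG rat 24, whose weight of 13.4 stood apart, also chosen after seeing the data). Without single arrays it was 12, 61, 17 and 14 for control rats 1, 2, 13 and 15, and 21, 136, 13, 14, 8 and 19 for GnRH+eCG rats 7, 8, 9, 19, 20 and 21.

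The trigger of ovulation was examined by comparing the hCG group with GnRH+eCG. A large part of the transcriptome changed, with 1440 probes higher and 1776 lower, 39.8% of those tested, and 753 of them by at least 2-fold. Prostaglandin synthase Ptgs2 rose from 7.64 ± 1.01 to 12.8 ± 0.65 (SD, n = 6 each, limma), 35.6-fold, at adjusted p = 3.3e-11. The epidermal growth factor receptor ligands Areg and Ereg rose 23.2-fold (log2 4.54 ± 0.37, SE) and 17.5-fold (4.13 ± 0.4). The progesterone receptor Pgr rose 18.1-fold (4.18 ± 0.23), and the transcription factor Runx1 24.1-fold (4.59 ± 0.63). In each of these genes all 6 hCG values lay above all 6 GnRH+eCG values, which the naming rule required. Areg was detected on 1 and Runx1 on 2 of the 6 GnRH+eCG arrays, so their folds are measured against signals mostly at background.

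Other large rises were Adcyap1, which encodes the neuropeptide PACAP (log2 4.04 ± 0.29), Trim36 (3.92 ± 0.29), Cthrc1 (3.7 ± 0.32), the cytokine receptor Tnfrsf12a (3.63 ± 0.47) and the glutathione transferase Gsta5 (3.46 ± 0.55). Trim36, Cthrc1 and Tnfrsf12a were detected on 1, 1 and 2 of the 6 GnRH+eCG arrays, where most signals were at background. Genes detected on 6 hCG arrays and 0 GnRH+eCG arrays were higher by at least 27-fold in Nefl, a neurofilament subunit, 24.6-fold in Akr1c2, 8.11-fold in the collagen receptor subunit Itga2, 6.42-fold in the chemokine Cxcl10 and 6.4-fold in Ptprn.

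The largest falls were in Cbfa2t3 (-2.69 ± 0.25), the inhibin beta-B subunit Inhbb (-2.47 ± 0.33), Sostdc1 (-2.24 ± 0.24), the coactivator Myocd (-2.08 ± 0.26), Galm (-2.05 ± 0.16), Trib2 (-2.03 ± 0.26), Aif1l (-2 ± 0.34), Cd83 (-1.99 ± 0.26), Bcl2l10 (-1.87 ± 0.43) and Rasd1 (-1.86 ± 0.22). Among the genes detected on 0 hCG arrays, Kcnk2 was at least 4.4-fold lower, the potassium channel Kcnj13 2.82-fold, Chst1 2.77-fold, RragB 2.76-fold and the prostaglandin E synthase Ptges 2.73-fold. A further probe of Inhbb changed by -1.67. Galm and Cd83 were detected on 2 of the 6 hCG arrays each.

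**Figure D2:**
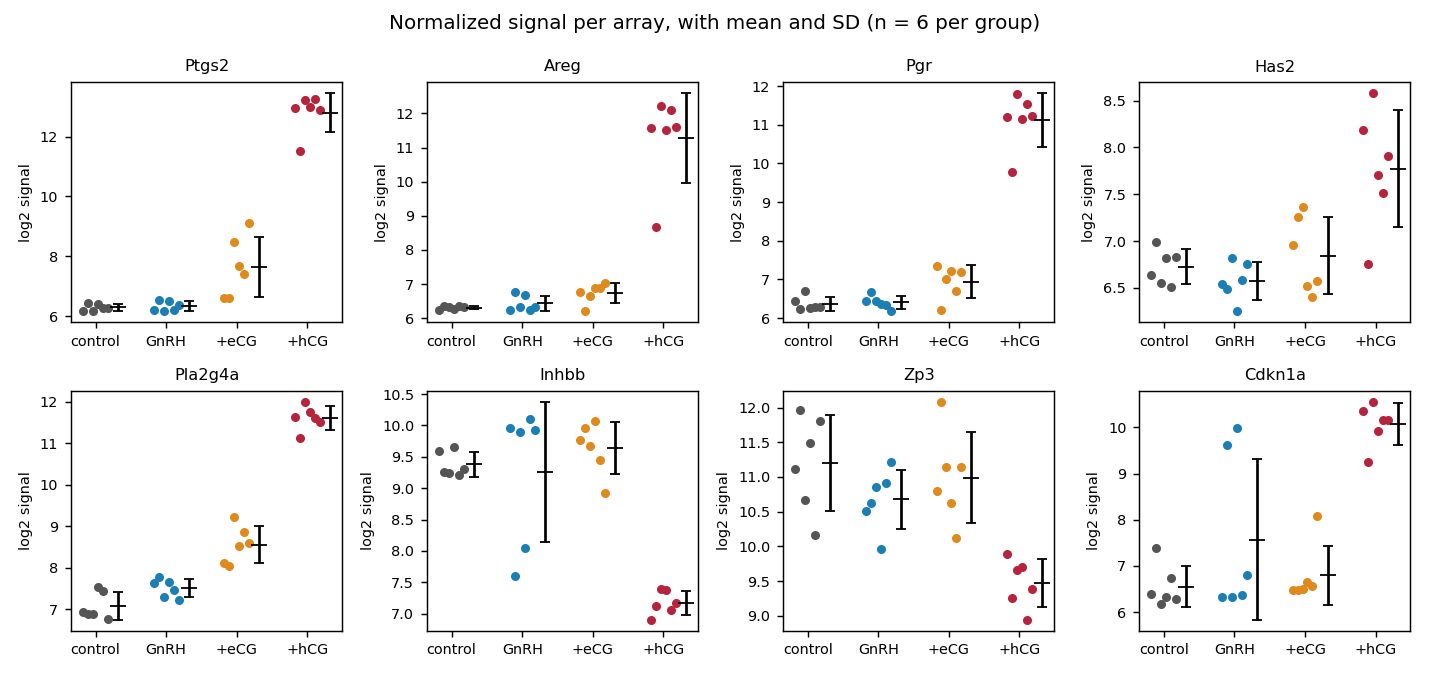
Normalized log2 signal (y axis) of 8 genes by group (x axis), with 1 point per rat and the group mean and SD beside the points (n = 6 per group). Ptgs2, Areg and Pgr are highest on the 6 hCG arrays. In GnRH rats 5 and 16 Cdkn1a lies near the hCG group, and Inhbb lies between the hCG and control means.

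Of the 8 measured cumulus expansion genes, 4 rose and 1 fell (median 0.86, camera adjusted p = 0.0215; adjusted p = 0.183 with an estimated correlation), and 5 rose and 1 fell adjusted over the list alone. Ptgs2, the hyaluronan synthase Has2 (0.93 ± 0.22, adjusted p = 0.00179), the hyaluronan receptor Cd44 (0.81 ± 0.12, 1.62e-05) and Vcan (0.53 ± 0.11, 0.000704) rose, and Ptges, which makes prostaglandin E from the product of Ptgs2, was at least 2.73-fold lower (0.000231). Has2 and Cd44 were each detected on 1 GnRH+eCG array. Adamts1 differed by 1.25 ± 0.75 (0.191), Sdc4 by 0.91 ± 0.4 (0.076) and Hmmr by -0.21 ± 0.26 (0.551). Hexosamine and hyaluronan precursor genes had 3 of 7 up and 1 down (median 0.33, camera 0.025; adjusted p = 0.183 with an estimated correlation), and 4 up and 1 down adjusted over the list alone. Gfpt2 was at least 4.09-fold higher, Uap1 rose by 2 ± 0.31 and Ugdh by 1.09 ± 0.25, and Ugp2 changed by -0.42 ± 0.11.

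EGF-like growth factor and MAPK response genes had 9 of 13 up and 1 down over all probes and adjusted over the list alone (median 1.43, camera adjusted p = 0.00012; adjusted p = 0.213 with an estimated correlation). Egfr rose by 1.3 ± 0.14 and the MAP kinase phosphatase Dusp5 was at least 4.31-fold higher. The member that fell was Adam17, a protease that sheds EGF-like ligands (-0.74 ± 0.11), named after its value was seen. The LH surge response had 10 of 13 up and 1 down by both adjustments (median 1.52, camera 0.000453; adjusted p = 0.183 with an estimated correlation), among them Cebpb (1.98 ± 0.31) and Errfi1 (3.22 ± 0.52). The member that fell was the nuclear receptor cofactor Nrip1 (-0.89 ± 0.26), named after its value was seen. Cyclic nucleotide and meiotic arrest genes went both ways, with 2 up and 4 down of 9, and 2 and 5 adjusted over the list alone (camera 0.72). The phosphodiesterases Pde10a and Pde4d rose by 2.54 ± 0.21 and 1.38 ± 0.22, and the natriuretic peptide precursor Nppc and the oocyte connexin Gja4 fell by 1.28 and 1.44, with Nppc detected on 1 hCG array.

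Oocyte genes were lower, with 15 of 16 down and 0 up, and 16 down adjusted over the list alone (median -1.11, camera adjusted p = 2.87e-05; adjusted p = 0.444 with an estimated correlation). The linker histone H1f8 changed by -1.5 ± 0.26, Npm2 by -1.13 ± 0.2, the zona pellucida gene Zp3 by -1.52 ± 0.3 and Gdf9 by -1.47 ± 0.3. FSH targets and cumulus granulosa markers had 8 of 15 down and 0 up, and 10 down adjusted over the list alone (median -0.85, camera 0.00339; adjusted p = 0.437 with an estimated correlation), with Amhr2 at -1.63 ± 0.2, Esr2 at least 1.77-fold lower and Ccnd2 at -1.03 ± 0.28. Cell cycle genes had 8 of 21 down and 1 up by both adjustments (median -0.49, camera 0.0129; adjusted p = 0.592 with an estimated correlation). Tyms fell by 1.19, Mcm6 by 1.28 and Ccne2 by 1.16, while the cyclin-dependent kinase inhibitor Cdkn1a, detected on 1 GnRH+eCG array, rose by 3.27 ± 0.52.

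Cholesterol biosynthesis genes had 6 of 13 up and 0 down by both adjustments (median 0.41, camera adjusted p = 0.0167; adjusted p = 0.592 with an estimated correlation), among them Idi1 (2.17 ± 0.58), Sc5d (0.92 ± 0.19), Nsdhl (1.12 ± 0.33) and Cyp51 (1.26 ± 0.41). Steroidogenesis was mixed, with 4 up and 3 down of 12, and 5 up and 3 down adjusted over the list alone (camera 0.409, but 0.0217 on the deposited values; adjusted p = 0.695 with an estimated correlation). The cholesterol transporter Star rose by 1.93 ± 0.51, Fdx1 by 1.11 ± 0.23, Scarb1 by 1.7 ± 0.48 and Stard4 by 0.85 ± 0.26. Erythrocyte markers differed by a median of -0.32 (0.755), leukocyte markers by -0.18 (0.719) and theca and stroma markers by 0.52 (0.793).

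With the rat-number sets as a block 3246 probes changed between the hCG group and GnRH+eCG, and 1013 changed within rats 1 to 12 and 1564 within rats 13 to 24. Oocyte genes had medians of -1.31 and -1.06 within these sets, the LH surge response 1.79 and 1.61, cumulus expansion 0.76 and 0.58, and cholesterol biosynthesis 0.72 and 0.29. Without quantile scaling the balance of calls shifted downward, to 879 higher and 2226 lower with median scaling, where the median of all probes moved to -0.15. On the deposited values, which also had no background correction, 582 were higher and 1917 lower, with that median at -0.16.

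**Figure D3:**
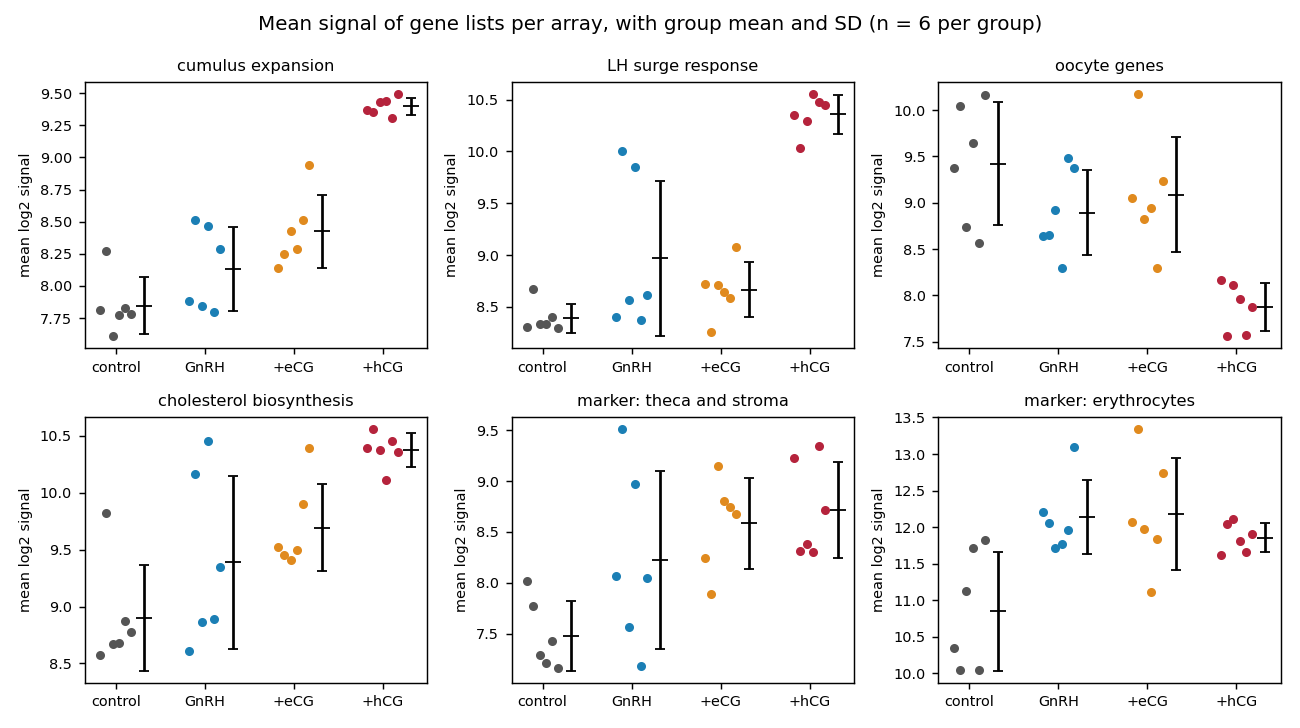
Mean log2 signal of the measured genes of 6 lists (y axis) by group (x axis), with 1 point per rat and the group mean and SD beside the points (n = 6 per group). Oocyte genes lie at 7.56 to 8.17 on the hCG arrays, and the LH surge response of GnRH rats 5 and 16 is 10 and 9.85 against 10.03 to 10.55 on the hCG arrays.

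The full sequence of hormones was compared with control. In the hCG group 1971 probes were higher and 2220 lower, 51.9% of those tested, and 1183 of them by at least 2-fold. Ptgs2, Ereg and Areg, detected on 0 control arrays, were at least 81.1-fold, 32.9-fold and 28.3-fold higher, and Nefl and Akr1c2 at least 27.1-fold and 25.5-fold. Runx1 rose from 6.54 ± 0.48 to 11.69 ± 0.21 (SD, n = 6 each, limma; adjusted p = 8.83e-07) and Pla2g4a from 7.07 ± 0.33 to 11.6 ± 0.29 (6.79e-15), with detection on 1 and 3 of the 6 control arrays. All 6 hCG values of each gene named for this comparison by size lay beyond all 6 control values, which the naming rule required.

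Further rises were in Gask1b (log2 4.5 ± 0.57, SE), Gsta5 (4.41 ± 0.55), the protease inhibitor A2m (4.38 ± 0.84), Osgin1 (4.3 ± 0.86), G0s2 (4.29 ± 0.71), Tnfrsf12a (4.26 ± 0.47), Pvr (4.21 ± 0.43) and the ectonucleotidase Nt5e (4.19 ± 0.49). Falls were in Gstm6l (-3.42 ± 0.88), Cd83 (-2.84 ± 0.26), Sostdc1 (-2.73 ± 0.24), Myocd (-2.72 ± 0.26), Cbfa2t3 (-2.67 ± 0.25), Bche (-2.63 ± 0.34), Btbd3 (-2.54 ± 0.25), anti-Müllerian hormone Amh (-2.36 ± 0.34), the BMP receptor Bmpr1b (-2.35 ± 0.27) and Ly6g6e (-2.24 ± 0.27). Of the genes that rose, A2m was detected on 2 control arrays and Gask1b, Osgin1, Tnfrsf12a and Pvr on 1 each, and of those that fell, Cd83 was detected on 2 hCG arrays and Bche and Ly6g6e on 1 each. A further probe of G0s2 differed by 2.8. Kcnk2, RragB, Ptges, Sspn and Suox, detected on 0 hCG arrays, were at least 7.1-fold, 3.97-fold, 3.61-fold, 3.19-fold and 3.17-fold lower.

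Cholesterol biosynthesis genes had 11 of 13 up and 0 down against control, and 13 up adjusted over the list alone (median 0.97, camera adjusted p = 0.000122; adjusted p = 0.439 with an estimated correlation). Steroidogenesis had 7 of 12 up and 1 down, and 7 up and 2 down adjusted over the list alone (median 1.02, camera 0.0363; adjusted p = 0.444 with an estimated correlation), a call lost without control rat 1 (0.0505). Cumulus expansion had 6 of 8 up and 1 down by both adjustments (median 1.14, camera 0.00829; adjusted p = 0.155 with an estimated correlation). EGF-like growth factor and MAPK response genes had 9 of 13 up and 1 down, and 10 up and 1 down adjusted over the list alone (median 1.62, camera 0.000453; adjusted p = 0.288 with an estimated correlation). The LH surge response had 9 up and 1 down of 13, and 9 up and 2 down adjusted over the list alone (median 1.78, camera 0.00122; adjusted p = 0.213 with an estimated correlation).

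Against control, oocyte genes had 16 of 16 down by both adjustments (median -1.61, camera adjusted p = 1.1e-05; adjusted p = 0.444 with an estimated correlation). FSH targets and cumulus granulosa markers had 8 of 15 down and 0 up, and 9 down adjusted over the list alone (median -0.86, camera 0.0109; adjusted p = 0.444 with an estimated correlation). Hexosamine and hyaluronan precursor genes had 4 up and 1 down of 7 by both adjustments (median 0.66, camera 0.0253; adjusted p = 0.183 with an estimated correlation). Proteases and inhibitors had 6 up and 1 down of 10 by both adjustments (median 0.92, camera 0.0444; adjusted p = 0.348 with an estimated correlation), a call lost with the rat-number sets as a block (0.0515) and without control rats 13 (0.0597) or 15 (0.0511) or hCG rats 10 (0.0567) or 23 (0.0592). Markers of other cells stood beside these: 4 theca and stroma markers rose and 1 fell of 7 (median 1.1, camera 0.166), 3 of 4 leukocyte markers rose (1.15, 0.0848) and 2 of 2 erythrocyte markers rose (1.01, 0.288). The theca and stroma and leukocyte lists were called on the deposited values (0.0132 and 0.0201) and with no filter (0.0444 and 0.0124; adjusted p = 0.567 and 0.48 with the filter and an estimated correlation).

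With the rat-number sets as a block 4271 probes changed between the hCG group and control, with 1583 within rats 1 to 12 and 3078 within rats 13 to 24. On the deposited values, without scaling or background correction, the split was 779 higher and 3170 lower, with the median of all probes at -0.26. Over all 5 comparisons camera called 40 of 105 list tests at the preset correlation, and 0 calls held with an estimated correlation. The fry test asks whether a list changed, not whether it changed more than other genes. For the hCG group against GnRH+eCG its adjusted p was 1.93e-08 for cumulus expansion, 6.01e-07 for the LH surge response and 0.00348 for oocyte genes. Cholesterol biosynthesis had 0.0741 there. For GnRH against control fry gave 0.00852 for hemoglobin genes, 0.00852 for housekeeping genes and 0.0489 for glycolysis. It gave 0.182 for oocyte genes and 0.369 for cell cycle genes. Housekeeping genes also had a fry adjusted p of 0.0343 for GnRH+eCG against control and 0.00113 for the hCG group against control. Median, mean and camera test differed in sign for 6 of the 105, none of them called by camera. For GnRH+eCG against GnRH these were the EGF-like growth factor list (median 0.04, mean -0.03, test downward) and the proteases (0.09, 0.01, downward), and for GnRH+eCG against control the FSH targets (0.05, -0.03, downward). For the hCG group they were leukocyte markers against GnRH+eCG (-0.18, 0.21, upward) and, against control, cyclic nucleotides (-0.23, 0.08, upward) and mural granulosa markers (-0.61, 0.07, downward).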

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

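The tests of array brightness and of an hCG array under a GnRH label, and both tests on GnRH+eCG against control, were chosen after the results were seen; the other tests on GnRH rats 5 and 16 and on oocyte genes were chosen after those patterns were seen but before their own values were. Of 204 groups of 6 values looked at, 30 had a value set apart by a gap that chance gives in about 1 group of 20, so about 10 would be expected.

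In the hCG group rat 11 was low in the EGF-like growth factor and MAPK response list, at 9.31 with the nearest rat at 10.13. Its signals were low for Areg (8.67, nearest 11.51), Ereg (9.62, nearest 11.54), Ptgs2 (11.51, nearest 12.88), Pgr (9.79, nearest 11.16) and Tnfrsf12a (9.51, nearest 10.89). In GnRH+eCG rat 21 was high in Runx1 (8.43, nearest 7.13), Trim36 (7.82, nearest 6.97), Cthrc1 (7.55, nearest 6.52) and the inflammation and innate immunity list (9.4, nearest 8.59). In the same group rat 8 was low in steroidogenesis, at 9.96 with the nearest rat at 10.81, and rat 7 was high in oviduct epithelium markers, at 8.7 with the nearest at 7.4.

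Among control rats, rat 2 was high in the list means of cumulus expansion (8.27), LH surge response (8.67), cholesterol biosynthesis (9.82) and inflammation and innate immunity (9.07). It was also high in Runx1 (7.51), A2m (9.47), Osgin1 (9.98), G0s2 (10.8), Tnfrsf12a (7.36) and Pvr (7.69). Control rat 1 was low in steroidogenesis (9.15) and Bola3 (7.81) and high in ribosomal proteins (11.57), oviduct epithelium markers (9.1) and Ech1 (9.98). Among GnRH rats, rat 16 was high in inflammation and innate immunity (8.63), rat 18 in erythrocyte markers (13.1) and rat 5 in endothelium markers (8.23).

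The array of hCG rat 24 lay unusually near the mean of the other 5 hCG arrays, noticed after the results were seen. Its SD from that mean over the tested probes was 0.14, against 0.27 to 0.56 for the other arrays and their groups, and its array weight was 13.4 against at most 1.76. Why it lies so near was not tested, so whether it counts as a separate rat with the full spread of the group is open. Without it 2839 probes changed against GnRH+eCG and 3901 against control.

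GnRH rats 5 and 16 stood apart from the other 4 GnRH rats. Over the 753 probes changed at least 2-fold by hCG, they lay at 44.6% and 51.5% of the way from the GnRH+eCG mean to the hCG mean, far below the lowest hCG array at 92.1%, which argues against an hCG array under a GnRH label. The other 16 arrays without hCG were both brighter and dimmer, at 25.3% to 37.9% of probes detected against 33.1% and 32.5%. They lay at 11% or lower on that scale, 33.6 points or more under these rats (SD of the 16, 9.6), which argues against array brightness. RNA yield was not analysed here and stays open. A partial response like that after hCG stays open, since their cumulus expansion means, 8.51 and 8.47, lay above the median of those 16 arrays (8.01) but the lower of them was -0.46 from the highest (8.94). Outside that test, their LH surge response means were 10 and 9.85, against 8.26 to 9.08 on those 16 arrays. Their FSH target means were 9.53 and 9.43, against 10.13 to 10.67. Hexosamine and hyaluronan precursors, at 8.64 and 8.63, lay within the range of those arrays, 8.26 to 8.71. Means of the EGF-like growth factor, protease and cell cycle lists also lay beyond those 16 arrays on the side of hCG. Glycolysis lay above both those 16 arrays and the hCG arrays, at 10.16 and 10.43 against at most 10.02 and 9.85. Housekeeping genes did so too, at 11.2 and 11.17 against at most 11.04 and 11.16. Cyclic nucleotide genes (9.31 and 9.15) and mural granulosa markers (9.62 and 9.54) lay below both. Cells of another type stay open too: 0 of 6 marker lists exceeded those 16 arrays on both rats, but theca and stroma markers, at 9.51 and 8.97 against a highest of 9.15, fell short by only 0.28 SD.

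Probes called in GnRH+eCG against control mostly kept their sign in the hCG group against GnRH. Of the 34 probes, 30 (88.2%) had the same sign, against 64.6% of all probes. These comparisons share no array, but both include the eCG step. The eCG step alone could give this agreement, so the test cannot show a likeness to hCG. A partial response like that after hCG, a hypothesis found and tested on the same data, stays open. Cells of another type could also account for the agreement. Of the 6 marker lists, 3 (theca and stroma, leukocytes and erythrocytes) were called higher by camera at the preset correlation in GnRH+eCG against control. They were not called with an estimated one (adjusted p = 0.288, 0.223 and 0.194). Of their measured members, 1 of 7, 1 of 4 and 2 of 2 were detected on all control arrays, with Ogn at 11.1, Fcer1g at 7.62 and Hba-a1 at 11.18 there. In GnRH+eCG, Ogn was not higher (10.74), against its list, and Cyp17a1 was also in another list.

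Oocyte genes were lower after hCG. Their median change was -0.93 or lower under the 3 alternative normalizations, which argues against normalization between arrays. A smaller oocyte share of the RNA, beside more cumulus RNA, would move all members alike. The SD of their changes was 1.08 times their median standard error (0.33 against 0.3). The limit set for that explanation was an SD no larger than that error. Members varied together between arrays (estimated correlation 0.85). Such shared variation widens each standard error but does not spread the changes of members apart, so the limit was lenient toward that explanation. The SD lay over it even so, with changes from -1.87 to -0.59, but short of the limit set for rejecting that explanation. The ratio therefore does not decide whether the members moved alike. A smaller share cannot be told apart from lower transcript levels, because the arrays carry no measure of cell number.

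Other groupings of the same 12 arrays were counted, 100 of the 462 possible for each comparison. For the hCG group 1 of 100, the real one, gave as many probes against GnRH+eCG (3216, highest other 1110). Against control it was likewise 1 of 100 (4191, highest other 2030). With 100 groupings counted no smaller share could be seen, so chance is unlikely but not excluded. For GnRH+eCG against control 3 of 100, the real one among them, gave as many as 34. Groupings that mixed the treatments gave 1103 and 326, and another gave 33. Although 3 of 100 met the limit set beforehand against chance, this count does not exclude it, since mixed groupings gave far more probes. The grouping with 1103 put control rats 1, 2, 13 and 15 with GnRH+eCG rats 8 and 21. They are the 6 of these arrays with positive scores on the second principal component. Their oocyte list means, 9.24 to 10.17, all lay above those of the rest of the 12 arrays, 8.3 to 9.05. The grouping thus followed the oocyte signal, which points to a structure of the samples other than treatment. For GnRH against control and GnRH+eCG against GnRH the real count was 0, so that 100 of 100 had to give as many and the count says nothing about chance; the highest others were 170 and 88. The split of the same arrays by rat number, 1 to 12 against 13 to 24, gave at most 2 probes with 12 arrays, but over all 24 arrays, with group in the limma model, 302 probes differed between these sets.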

How the results depend on the processing

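The runs without GnRH rats 5 and 16, and with array weights but without hCG rat 24, were chosen after the results were seen. No paired analysis was possible because the groups share no rat numbers in the labels. The cause of each move below was not tested, except where fewer probes or arrays entered the fit. For GnRH+eCG against control, 34 probes became 4 on the deposited values, 22 with no filter, 17 with detection on all 24 arrays, 0 within rats 1 to 12, 15 within rats 13 to 24, 20 with only the 12 arrays compared, 540 with array weights (480 without hCG rat 24), 13 at 2-fold or more, 4 at adjusted p under 0.01 and 187 without GnRH rats 5 and 16. Leaving out single arrays gave 8 to 136: 12, 61, 17 and 14 without control rats 1, 2, 13 and 15, and 21, 136, 13, 14, 8 and 19 without GnRH+eCG rats 7, 8, 9, 19, 20 and 21. For GnRH+eCG against GnRH, 0 became 4 with median scaling, 26 with array weights (12 without hCG rat 24), and 3, 1 and 2 without GnRH+eCG rats 7 and 8 and GnRH rat 18, a range of 0 to 3. GnRH against control gave 0 in each run and each leave-one-out. For the hCG group against GnRH+eCG, 3216 became 1719 with detection on all 24 arrays, 1013 within rats 1 to 12 and 1564 within rats 13 to 24, 753 at 2-fold or more and 2046 at adjusted p under 0.01, with 2839 to 3141 on leaving out single arrays. Against control, 4191 became 2293 with detection on all 24 arrays, 1583 within rats 1 to 12 and 1183 at 2-fold or more, with 3882 to 4138 on leaving out single arrays. The share of calls that were higher moved from 61.8% to 80% with median scaling and 75% on the deposited values for GnRH+eCG against control, but to 38.5% at 2-fold or more and 43.8% without control rat 3. It moved from 44.8% to 28.3% with median scaling, 23.3% on the deposited values, 50.5% with no filter and 54.6% within rats 1 to 12 for the hCG group against GnRH+eCG. Against control it moved from 47% to 19.7% on the deposited values and 54% within rats 1 to 12. List calls went from 40 to 0 with an estimated correlation and lay between 37 and 44 on leaving out single arrays. The deposited values added 17 calls, no filter 13 and median scaling 8, with 1 lost. Without GnRH rats 5 and 16 the test turned direction in 3 lists called with or without them: cholesterol biosynthesis (-0.01) and cell cycle (0.02) in GnRH against control, and EGF-like growth factor and MAPK response (median 0.04, then 0.19) in GnRH+eCG against GnRH. Uncalled lists turned too, among them FSH targets in both comparisons (-0.24 to 0.13, and 0.23 to -0.17). Of 161 named gene results, 161 kept direction and side of the threshold with rats 1 to 12 and 13 to 24 as a block, and 20 lost their call on the deposited values. Single arrays that ended gene calls for GnRH+eCG against control were, by rat number: 1, 7, 9, 19 and 20 for Afdn; 1, 3, 7, 15, 19, 20 and 21 for Bzw1; 1, 7, 9, 13, 14, 15, 19, 20 and 21 for Ech1 and Fbxl20; 1, 3, 7, 9, 13, 14, 15, 19, 20 and 21 for Mrpl49 and Tmed10; 1, 2, 9, 15, 19, 20 and 21 for Pak1ip1; 1, 3, 7, 13, 14, 15, 19, 20 and 21 for Pde10a; 7, 9, 13, 15, 19, 20 and 21 for Sspn; and 1, 3, 9, 13, 15, 19, 20 and 21 for Tp53i11. Signal over background limits dim probes, since 36.4% of probes passed the filter.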

Other observations

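Lists not called in the hCG group against GnRH+eCG, where 39.8% of all tested probes changed, held single genes that did. Of 10 proteases and inhibitors, 3 rose and 0 fell by both adjustments (median 0.66, camera adjusted p = 0.0701, but 0.0162 with median scaling and 0.0043 on the deposited values; adjusted p = 0.424 with an estimated correlation), with the metalloproteinase inhibitors Timp3 and Timp1 up by 1.24 ± 0.13 and 1.61 ± 0.52 (SE, log2) and Ctsb by 0.7 ± 0.18. Of 4 measured inflammation genes, from a list of 20, 2 rose (median 0.36, camera 0.501), Cd14 (detected on 2 of 6 GnRH+eCG arrays) by 0.98 ± 0.17 and Cxcl1 by 1.5 ± 0.52. Glycolysis genes had 1 up and 6 down of 15 (median -0.16, camera 0.17, but 0.0127 with no filter; adjusted p = 0.664 with an estimated correlation), with Pfkm at -1.68 ± 0.25, Gpi at -0.71 ± 0.15, Ldhb at -0.43 ± 0.11 and Pdk3 at -0.59 ± 0.16. Ribosomal protein genes had 0 of 20 past the threshold, and 2 of 9 housekeeping genes rose, Ywhaz by 0.55 ± 0.12 and Hprt1 by 0.34 ± 0.13, with 1 rising adjusted over the list alone.

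Markers of other cells moved in different directions in that comparison. The leukocyte gene S100a8 rose by 1.5 ± 0.33 and the endothelial gene Esam, detected on 1 of 6 GnRH+eCG arrays, by 0.88 ± 0.34 (1 of 2 measured, camera adjusted p = 0.366). The epithelial gene Cdh1 was called lower (1 of 3 oviduct markers, camera 0.501). It was detected on only 2 of 6 GnRH+eCG arrays and 0 hCG arrays, mostly at background in both groups. The androgen synthesis enzyme Cyp17a1 changed by -1.83 ± 0.57. It was detected on 4 of 6 GnRH+eCG arrays, where its SD was 1.9, and on 3 of 6 hCG arrays. Mural granulosa markers, of which 7 of 7 are in another list, had 1 up and 2 down (median -0.75, camera 0.477), with Hsd17b1 at -1 ± 0.38. Leaving out any 1 of these rats ended a call: 7, 9, 10, 19, 20, 21 and 24 for Esam (adjusted p up to 0.124), 7, 8, 10 and 23 for Cdh1 (0.0902), 7, 8, 9, 11, 19, 20, 22 and 24 for Hsd17b1 (0.111), 7, 8, 9 and 19 for Cxcl1 (0.0621), and 7, 9, 10, 11, 12, 19, 21, 22 and 24 for Hprt1 (0.0909).

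GnRH rats 5 and 16 carried part of the hCG profile and lacked another part, in genes chosen after their values were seen. Cdkn1a stood at 9.61 and 9.99 in these rats, with group means of 6.55 in control and 10.07 after hCG. Inhbb stood at 7.6 and 8.05, with 9.38 in control and 7.17 after hCG, and Runx1 at 10.82 and 10.8, with 6.54 and 11.69. Ptgs2, at 6.55 and 6.51, lay near the control mean of 6.29 and far from 12.8 after hCG, and likewise Areg at 6.76 and 6.69 (6.31 and 11.28) and Pgr at 6.67 and 6.37 (6.37 and 11.12). The labels give no hormone levels or cycle stage at collection that would place these 2 rats.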
